A study of Rattus norvegicus with 12 samples.

How the data were processed

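RNA of the left ventricle of 12 rat heart samples was measured on single-channel expression arrays, 6 after 7 weeks of treadmill running and 6 sedentary, per the labels. The values are the intensity per probe set as deposited by the authors, on a linear scale. The array software, the scanner, the background correction, the scaling and any detection calls are not given in the sources used here, nor are the age, sex or strain of the rats, the running schedule, or when tissue was taken in relation to the last run and to the time of day. The trimmed means of the 12 arrays (2% trimmed) differed by a factor of at most 1.05, so the deposited scaling was kept. An unknown global scaling of this kind would hide a change in total RNA per cell, and all differences are relative to the other probe sets. The unnamed probe set X80130cds_i_at was at the ceiling on every array (64883 to 64994).

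Each array was assigned to its group by its title. The numbers in the titles are not shared between groups, so no pairing was used, and no batch or scan date is given in the labels. The fixed design was limma on log2(intensity + pseudocount), with the pseudocount at the 20th percentile of all values (363), values below 0 set to 0, and probe sets kept when their mean over the 12 arrays was above the 25th percentile of those means (434). This kept 6555 of 8740 probe sets. The fit used lmFit and eBayes with a mean-variance trend (limma 3.58.1, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over the kept probe sets and a threshold of 0.05. Choices listed as fixed were made before the data were examined.

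Gene names came from the platform's annotation. Of the 8740 probe sets, 7006 named 1 gene, 308 named several and 1426 were not in it and are unnamed here. Of the probe sets with 1 gene, 6985 matched a RefSeq gene table by Entrez ID, and no symbol changed. No gene was named from a probe set with several genes. For 3876 genes the probe set with the highest mean over the 12 arrays stood for the gene, and the text says where other measured probe sets of a named gene had the opposite sign or, for a gene past a threshold, a much smaller difference.

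Named genes were fixed by rule. They were, in each direction, the 12 genes of largest change among those past the threshold, filled by the smallest unadjusted p where fewer passed; every measured gene of a fixed panel of hypertrophy, metabolism and signalling genes; and members of a gene list past 0.05 when adjusted over the list alone, at most 4 per list. Dbp, Bmal1, Hspd1, P4hb, Dnajb5, Hbb, Alas2, Cst3, Bex3, Ppt1, Akip1 and the genes named only in the closing section fall outside the rule and were chosen after their values were seen. Gene lists were tested with camera on 1 probe set per gene, with a preset correlation of 0.01, and adjusted over the 27 fixed lists with at least 5 measured members. Beside it stand camera with the estimated correlation and fry. Fry does not compare a list with other genes, so its test for change in either direction can pass on a few changed members. List medians were set against 10000 random lists matched on mean expression.

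The code was tested on simulated data. Over 10 simulated comparisons of 6 against 6 arrays with the 6555 probe sets and 200 changed ones, 61.9% of those changed by 0.25 log2 were recovered, 94.0% at 0.5 and 99.8% at 1. Of the calls, 4.55% were false. A list shifted by 0.15 was called in 10 of 10 runs, and 0.1 unshifted lists per run were called. The simulated noise was independent between genes and equal across arrays, so the simulation does not test the effect of correlation within a list. Nor does it show how correlation, a deviating array or fewer changed probe sets would alter the shares recovered and false.

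Alternatives fixed beforehand were other pseudocounts, a floor, other filters on dim probe sets, quantile and median scaling, eBayes without trend or with robust settings, array weights, an exact rank-sum test, a threshold of 0.10, other list tests and leaving out each array in turn. Leaving out sedentary 16 and 17 together and exercised 4 and 5 together was chosen after seeing the data, as were camera with an estimated correlation on arrays left out and the first principal component without sedentary 17. The planned check of RNA quality from control probe sets could not be run, since the table used here holds no control probe sets and none annotated to Gapdh, and the fit with that ratio as a covariate was not run either. The effects of the alternatives are given in the closing section.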

Results

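Gene expression was measured in the left ventricle of the rat heart after 7 weeks of treadmill running and in sedentary rats, in a study of the growth of the heart under exercise. Total RNA of 6 exercised and 6 sedentary samples was hybridised to 1 single-channel array per sample. Samples are named here by their group and the number in their label (exercised 1, 4, 5, 7, 8 and 9, sedentary 13, 16, 17, 21, 23 and 24). The labels do not state that each number is a separate animal, so the p-values measure the spread between these samples, which may be partly technical. The table held an intensity for 8740 probe sets on each of the 12 arrays. The median intensity of an array lay between 840 and 875 and its trimmed mean between 1465 and 1534, so the arrays were on a common scale. The number of arrays limits the precision. Differences are exercised minus sedentary on the log2(intensity + 363) scale, which understates the change of dim probe sets, and intensities are mean ± SD with n = 6 per group. No genome build was given in the sources used here, so genes are identified by symbol and probe set without coordinates.

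The question of the single comparison in the design was which ventricular transcripts differ after training. Lyz2, the lysozyme of macrophages and other myeloid cells, had the largest increase among the genes that passed the test, from 2401 ± 297 in sedentary to 5421 ± 2104 in exercised samples, a log2 difference of 0.997 ± 0.18 (SE, n = 6, limma adjusted p = 0.0404). Nmrk2, a muscle kinase that turns nicotinamide riboside into an NAD precursor, rose by 0.61 ± 0.076 (626 ± 55.3 to 1151 ± 185, adjusted p = 0.00267). Xdh, xanthine dehydrogenase of purine breakdown, rose by 0.55 ± 0.065 (1601 ± 192 to 2511 ± 186, adjusted p = 0.00191). Hspe1, the mitochondrial co-chaperonin, rose by 0.52 ± 0.060 (5585 ± 280 to 8186 ± 694, adjusted p = 0.00191). Ucp2, a carrier of the mitochondrial inner membrane, fell by 0.45 ± 0.087 on its brighter probe set (17002 ± 2060 to 12325 ± 1387, adjusted p = 0.0404), and its other one gave -0.19 (adjusted p = 0.151).

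Other genes that rose were Hsph1, a large heat shock protein (log2 difference 0.60), Csrp3, the muscle LIM protein of the Z-disc (0.58), the sulfotransferase Sult1a1 (0.46), the endocytic adaptor Dab2 (0.43), the phosphatase Ptp4a1 (0.40), the complement protease C1s (0.39), the LIM protein Csrp2 (0.36) and Acsl4, which activates arachidonic acid (0.32). Their limma adjusted p lay between 0.0192 for Csrp2 and 0.0404 for Dab2, C1s and Acsl4. The other probe set of Hsph1 gave 0.21 and that of Sult1a1 0.43, with adjusted p of 0.0916 and 0.0655. The LIM protein Crip2 fell by 0.24 ± 0.041 (adjusted p = 0.0302). On the probe set that stood for it, each of these genes was higher, or for Ucp2 and Crip2 lower, than the sedentary mean in 6 of 6 exercised samples. The probe sets of the leading genes were rc_AA892775_at for Lyz2, rc_AI639060_at for Nmrk2, rc_AI172247_at for Xdh, rc_AI170613_g_at for Hspe1 and AB010743_at for Ucp2.

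In all, 21 of 6555 tested probe sets passed an adjusted p of 0.05 (limma with a mean-variance trend and Benjamini-Hochberg adjustment, two-sided), 18 higher and 3 lower in exercised samples, and they named 19 genes and 1 unnamed probe set. At an unadjusted p under 0.05 there were 1060 probe sets, 607 higher and 453 lower, where chance gives 328. The exercised and sedentary values of 136 tested probe sets did not overlap, or 2.07%, where chance gives 0.216%, and 19 of the 21 passing probe sets were among them. Leaving out 1 array moved the number passing to 3 without sedentary 23, 4 without exercised 5 or sedentary 24, 6 without sedentary 16, 8 without exercised 7, 12 without exercised 9, 13 without sedentary 21, 35 without exercised 1 and 37 without sedentary 13. Of the 14 genes above that passed, Hspe1, Xdh and Nmrk2 did so in all 12 of these fits, and the other 11 did not pass without sedentary 23. They were lost in further fits too. Csrp2 and Hsph1 passed in 9 of the 12 fits, and Crip2 and Sult1a1 in 6. Lyz2, C1s, Ptp4a1 and Csrp3 passed in 4, Ucp2 and Dab2 in 3 and Acsl4 in 2.

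**Figure D1:**
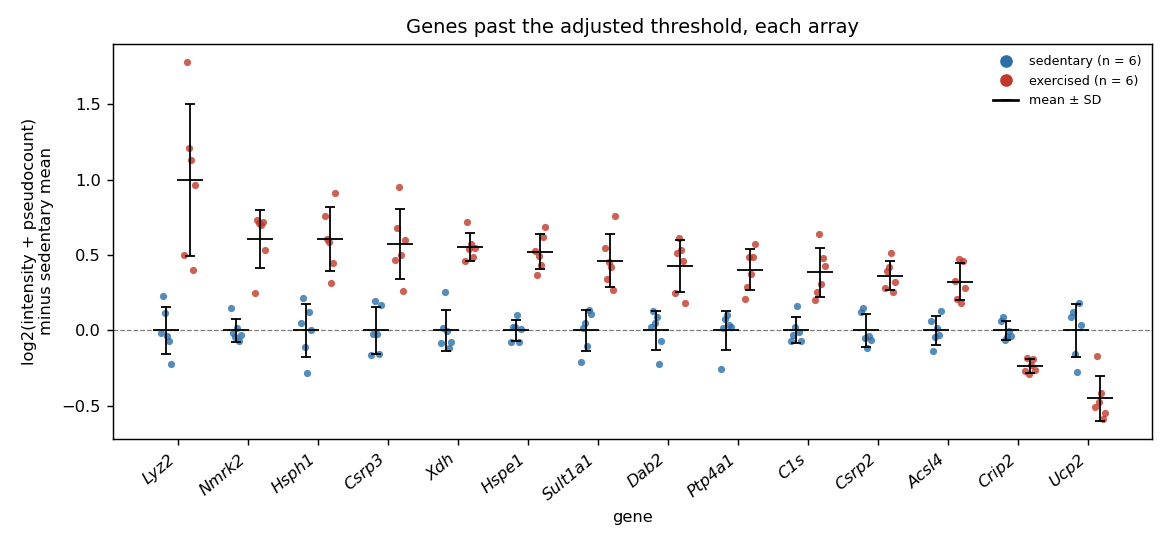
Points are the 6 sedentary and 6 exercised arrays for each gene past the adjusted threshold, as log2(intensity + 363) minus the sedentary mean, and bars are mean ± SD. The mean difference runs from 0.997 for Lyz2 to -0.45 for Ucp2, and the spread among exercised arrays is widest for Lyz2.

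Some genes were fixed for naming although they did not pass the threshold. The lower of them were the magnesium transporter Slc41a3 (log2 difference -0.35, limma adjusted p = 0.0888), the serotonin receptor Htr2b (-0.28, 0.0617), Gm2a (-0.23, 0.0920), Slc22a2 (-0.23, 0.0916), the BMP receptor Bmpr1a (-0.21, 0.0920), Dlg3 (-0.19, 0.0910), the phosphatase Dusp5 (-0.16, 0.0542) and Pawr (-0.14, 0.0787). Further passing probe sets named genes outside the naming rule, and these were chosen after their values were seen. They were Cst3, a protease inhibitor (0.45, adjusted p = 0.0276, with 0.40 and 0.0546 for its brighter probe set), Bex3 (0.25, 0.0404), the lysosomal thioesterase Ppt1 (0.22, 0.0404) and 1 probe set of Akip1 (0.88, 0.0111). The probe sets of Akip1 disagreed, since its other ones gave 0.01 and 0.00. Idh2, the mitochondrial isocitrate dehydrogenase, was lower on both of its probe sets, at -0.28 (adjusted p = 0.0404) and, on the brighter one, -0.18 (0.0617).

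Chaperones differed in both directions, the lower ones only when adjusted over their list alone. Of 25 measured heat shock proteins and chaperones, Hspe1 and Hsph1 rose and 23 did not pass over all probe sets. Adjusted over the list alone, 5 were higher and 2 lower. Besides Hspe1 and Hsph1, the higher ones were the small heat shock protein Hspb6 (log2 difference 0.39 ± 0.079, list-adjusted p = 0.00134), the mitochondrial chaperonin Hspd1 (0.27 ± 0.057, 0.00183) and the disulfide isomerase P4hb (0.24 ± 0.075, 0.0247). The lower ones were the inducible chaperone Hspa1a (-0.26 ± 0.053, 0.00134) and Dnajb5 (-0.22 ± 0.060, 0.00909). The list as a whole was not shifted, with a median of 0.00 and a camera adjusted p of 0.573, whereas fry's test for change in either direction gave an adjusted p of 1.72e-06. That test does not compare the list with other genes. It may restate the change of members such as Hspe1 and Hsph1, and the same limit holds for its use on the lists below. The Hspa1a probe set can share signal with near-identical Hsp70 genes, so its identity is uncertain, and Hspa1b was not analysed here.

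Genes of the ribosome and of protein synthesis were slightly higher together. Of 43 measured members, 42 were higher and 1 lower by sign, with a median log2 difference of 0.15. The 4 members with the smallest p were Rpl27a (0.20 ± 0.050), Rpl31 (0.28 ± 0.073), Eef2 (0.20 ± 0.052) and Rpl35 (0.26 ± 0.069), each with a list-adjusted p of 0.0175. No member passed over all probe sets, and 19 passed, all higher, when adjusted over the list alone. Of the other Eef2 probe sets, 1 went the other way (-0.08). The list was called by camera with a preset correlation of 0.01 (adjusted p = 1.51e-11), and this call was lost with the correlation estimated from the data (adjusted p = 0.449 with an estimated correlation). It was the only one of 27 lists called, and fry's directional test gave an adjusted p of 0.0450.

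**Figure D2:**
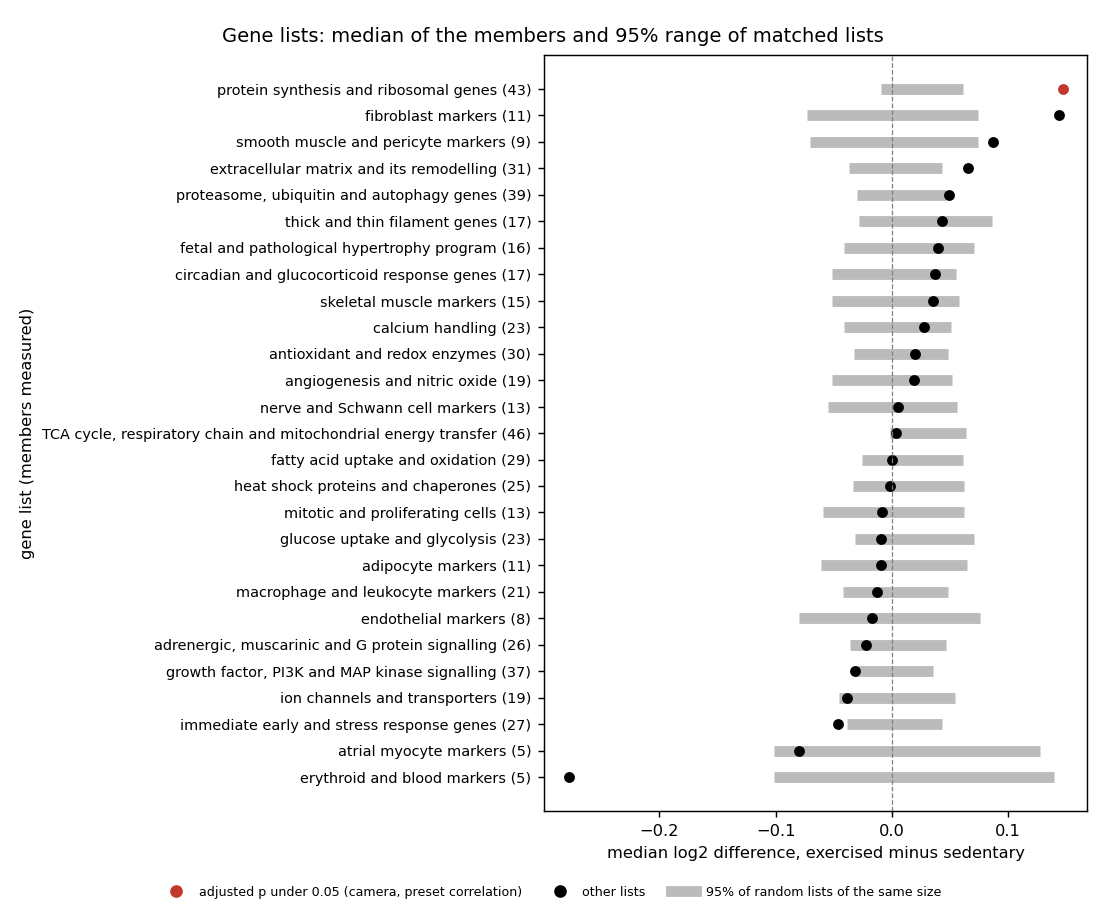
Dots are the median log2 difference of the measured members of each of 27 gene lists, and grey bars hold 95% of 10000 random lists of the same size matched on mean expression. The ribosomal list lies at 0.15, above its random range, which ends at 0.06. The fibroblast, smooth muscle, matrix and proteasome lists also lie above their ranges. The erythroid list, at -0.28, and the immediate early and growth factor lists lie below theirs.

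Of 17 measured thick and thin filament genes, Csrp3 rose and 16 did not pass, and 13 were higher and 4 lower by sign. The list had a median of 0.04 and a camera adjusted p of 0.0969, so it was not called, whereas fry's test for change in either direction gave an adjusted p of 0.00620 and its directional test 0.0602. The mean of the list, centred over the arrays, lay between 0.01 and 0.11 log2 on the 6 exercised and between -0.06 and -0.03 on the 6 sedentary arrays. Csrp3 went from 11745 ± 1304 to 17787 ± 2996. The alpha and beta heavy chains of myosin gave -0.04 ± 0.037 for Myh6 and 0.04 ± 0.029 for Myh7, with limma adjusted p of 0.632 and 0.516. Other probe sets gave -0.11 and 0.01 for Myh6 and 0.14 for Myh7, and those of both genes can share signal. Under quantile normalization the adjusted p of Csrp3 was 0.0683.

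Of 16 measured genes of the fetal and pathological hypertrophy program, none passed over all probe sets or over the list alone (median 0.04, camera adjusted p = 0.407). Skeletal alpha actin, Acta1, went from 7027 ± 1778 to 12572 ± 5314 (log2 difference 0.73 ± 0.25, limma adjusted p = 0.169), and Ankrd1, a stretch-responsive repeat protein, gave 0.21 ± 0.092 (0.280). The natriuretic peptides gave 0.29 ± 0.34 for Nppa (0.680) and 0.05 ± 0.11 for Nppb (0.827), and the other Nppa probe sets gave 0.67 to 0.88. The atrial light chains Myl7 and Myl4 gave -0.36 ± 0.35 (0.613) and -0.29 ± 0.14 (0.328). Sedentary 16 had a Myl7 intensity of 8652, against 1136 to 1923 on the other sedentary arrays, and without it the difference of Myl7 was 0.04, that of Myl4 -0.14 and that of Nppa 0.57. The difference of Nppa was 0.087 without exercised 4, and -0.010 without exercised 4 and 5, a pair chosen after seeing the data. Of 5 measured atrial markers Pam, a peptide amidating enzyme, was higher over the list alone (0.21 ± 0.067, list-adjusted p = 0.0331, with 0.03 to 0.22 on its other probe sets), and the list was not called (median -0.08, camera adjusted p = 0.809, and 0.04 and 0.716 without sedentary 16).

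**Figure D3:**
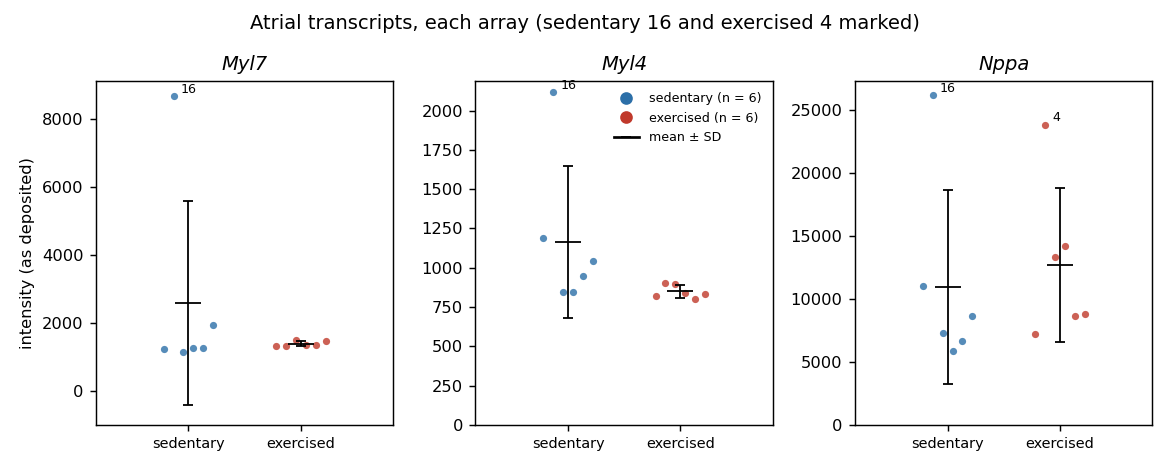
Points are the intensities of Myl7, Myl4 and Nppa on the 6 sedentary and 6 exercised arrays, and bars are mean ± SD. Sedentary 16 lies at 8652 for Myl7, 2117 for Myl4 and 26157 for Nppa, and exercised 4 at 23843 for Nppa.

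Among 29 measured genes of fatty acid uptake and oxidation, Ucp2 fell and 28 did not pass (median 0.00, camera adjusted p = 0.809), and fry's test for change in either direction gave an adjusted p of 0.0401. Cpt1b, which moves fatty acids into mitochondria, gave 0.00 ± 0.066, Pdk4 0.24 ± 0.15 and Ucp3 -0.07 ± 0.045, with limma adjusted p of 0.999, 0.447 and 0.438, and the other Ucp3 probe set gave 0.01. The difference of Pdk4 was 0.096 without exercised 9 and 0.16 without sedentary 17. Among 23 genes of glucose uptake and glycolysis, the monocarboxylate transporter Slc16a1 was higher over the list alone (0.46 ± 0.098, list-adjusted p = 0.00802, with 0.18 on its other probe set), the glucose transporter Slc2a4 gave -0.12 ± 0.11, and the list was not shifted (median -0.01, camera adjusted p = 0.809). Among 46 genes of the citric acid cycle and respiratory chain, Idh2 was lower over the list alone (list-adjusted p = 0.0189) and 45 did not pass there, with a list median of 0.00 and a camera adjusted p of 0.407. Of 30 antioxidant enzymes, extracellular Sod3 was higher (0.19 ± 0.052, with 0.03 on its other probe set) and the glutathione transferase Gsta3 lower (-0.28 ± 0.074) over the list alone, both with a list-adjusted p of 0.0359, while mitochondrial Sod2 gave 0.02 ± 0.17 (camera adjusted p of the list 0.809, median 0.02).

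Calcium handling, excitation and signalling genes had no member past the threshold. The calcium pump Atp2a2 gave -0.10 ± 0.067 and its other probe sets -0.02 to 0.18, and its inhibitor Pln gave 0.08 ± 0.049 (list of 23, median 0.03, camera adjusted p = 0.736). The potassium channel Kcnd2 gave 0.05 ± 0.045 and its other probe set -0.08, with 0.010 without sedentary 17 (list of 19 channels and transporters, median -0.04, 0.407). The receptor Adrb1 gave -0.14 ± 0.071, and -0.069 without sedentary 17 (list of 26 adrenergic and G protein genes, median -0.02, 0.236). Igf1 gave -0.01 ± 0.078, with 1 of its other probe sets at 0.33, and Cebpb -0.01 ± 0.052, with its other probe set at 0.08 (list of 37 growth factor and kinase genes, median -0.03, 0.104). Vegfa gave -0.16 ± 0.064 with a limma adjusted p of 0.234 (list of 19 angiogenesis genes, median 0.02, 0.802).

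Clock genes differed between the groups when adjusted over their list alone. Dbp, a transcription factor driven by the clock, went from 1505 ± 520 to 2982 ± 1395 (log2 difference 0.76 ± 0.27, list-adjusted p = 0.0355), Nr1d2 from 766 ± 247 to 1360 ± 484 (0.59 ± 0.18, 0.0256) and Bhlhe41 from 708 ± 86.2 to 1014 ± 228 (0.35 ± 0.093, 0.0177). Bmal1, whose product activates clock-controlled genes, went from 1051 ± 119 to 898 ± 74.4 (-0.16 ± 0.057, 0.0355), and its dimmer probe set gave -0.08 ± 0.11 (limma adjusted p = 0.701). Hsd11b1, which regenerates active glucocorticoid, gave 0.28 ± 0.074 and Glul 0.23 ± 0.067 (list-adjusted p = 0.0177 and 0.0229). Of 17 measured circadian and glucocorticoid response genes, none passed over all probe sets, and 5 were higher and 1 lower over the list alone. The list was not called by camera (median 0.04, adjusted p = 0.104), and fry's directional test gave an adjusted p of 0.00387. With group means removed, the mean of Dbp, Nr1d2 and Bhlhe41 went with the number in the sample's label (Spearman rho = 0.811, Pearson r = 0.754, permutation p = 0.00067 and 0.00116).

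**Figure D4:**
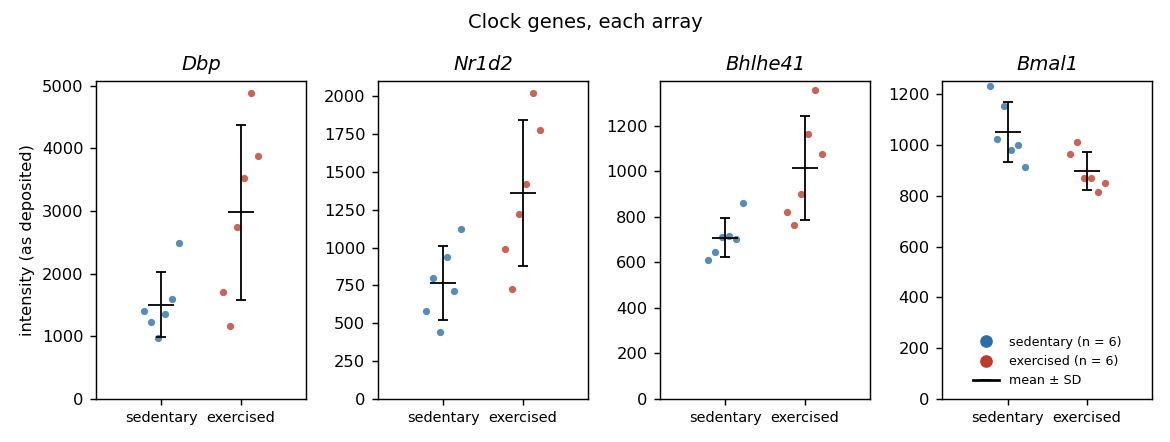
Points are the intensities of Dbp, Nr1d2, Bhlhe41 and Bmal1 on the 6 sedentary and 6 exercised arrays, and bars are mean ± SD. Dbp averages 2982 in exercised and 1505 in sedentary samples, with overlapping ranges, and Bmal1 averages 898 and 1051.

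With all 12 arrays, no list of markers of another cell type was called by camera. With arrays left out, some were, each with the preset correlation alone. Fibroblast markers were called higher without sedentary 17 (adjusted p = 0.0405), exercised 1 (0.0372), exercised 9 (0.0338) or sedentary 16 and 17 (0.00894), the last chosen after seeing the data, and in these fits had adjusted p of 0.365 to 0.481 with an estimated correlation. Smooth muscle markers were called higher without sedentary 17 (0.0405) or sedentary 16 and 17 (0.000603), and erythroid markers lower without exercised 1 (0.0372) or sedentary 17 (0.0405). In these fits the adjusted p with an estimated correlation was 0.474 and 0.365 for smooth muscle and 0.442 and 0.446 for erythroid markers. Among 21 macrophage and leukocyte markers Lyz2 rose and the complement gene C1qb was higher over the list alone (0.37 ± 0.093, list-adjusted p = 0.0144), yet 12 of the 21 were lower by sign and the list median was -0.01 (camera adjusted p = 0.809). Fry's test for change in either direction gave an adjusted p of 0.000776 for this list. Fibroblast markers had a median of 0.14 over 11 genes and extracellular matrix genes 0.07 over 31, with camera adjusted p of 0.0964 and 0.0969. The matrix list was called without exercised 9 (0.0338, and adjusted p = 0.422 with an estimated correlation). With 1 array left out the fibroblast median ran from 0.09, without exercised 4, sedentary 23 or sedentary 24, to 0.20 without sedentary 17, and the matrix median from 0.04 without sedentary 17 to 0.09 without exercised 1. Without exercised 4 and 5, the arrays low in haemoglobin transcripts, they were 0.06 and 0.03 (camera adjusted p = 0.656 for both). Smooth muscle markers had a median of 0.09 over 9 genes (0.0969), with Actg2 higher over the list alone (0.17 ± 0.040, list-adjusted p = 0.00627). Erythroid markers had a median of -0.28 over 5 genes (0.0964), with 4 lower and 1 higher by sign. The median was the difference of Alas2, which went from 2891 ± 403 to 2320 ± 341 (-0.28 ± 0.099, limma adjusted p = 0.182). The haemoglobin gene Hbb had intensities of 15784 on exercised 4 and 8786 on exercised 5 against 28362 to 37794 on the other 10 arrays.

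Immediate early genes had a median of -0.05 over 27 genes (camera adjusted p = 0.0964) and were called lower without exercised 1 (0.0372), sedentary 13 (0.0378) or sedentary 17 (0.0405), and there had adjusted p of 0.358 to 0.474 with an estimated correlation. Proteasome, ubiquitin and autophagy genes had a median of 0.05 over 39 (0.0969) and were called higher without exercised 1 (0.0456), exercised 4 (0.0314) or exercised 4 and 5 (0.0171), and there had adjusted p of 0.442 to 0.598 with an estimated correlation. Endothelial markers had a median of -0.02 over 8 genes (0.763), mitotic genes -0.01 over 13 (0.652) and skeletal muscle markers 0.04 over 15 (0.701). Adipocyte markers had a median of -0.01 over 11 genes (0.836), with Fabp4, a fatty acid binding protein also of capillary endothelium, higher over the list alone (0.26 ± 0.066, list-adjusted p = 0.0186). Nerve and Schwann cell markers had a median of 0.00 over 13 genes (0.809, and 0.0401 by fry's test for change in either direction), with Cnp higher over the list alone (0.18 ± 0.040, list-adjusted p = 0.00667). The median and mean had opposite signs for the heat shock, macrophage, glucose, fatty acid, mitochondrial and adipocyte lists, each within 0.05 of 0.

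Array measures were compared between groups with two-sided exact permutation tests and Benjamini-Hochberg adjustment over 6 measures. The median and trimmed mean intensity gave exact p = 0.502 and 0.0584 (adjusted 0.753 and 0.175). The first principal component of the log2 values separated the groups (-3.54 ± 2.03 in exercised and 3.54 ± 8.11 in sedentary samples, exact p = 0.00216, adjusted 0.0130). Without sedentary 17, which lay at 19.98, the same component averaged 0.25 ± 1.06 in the other 5 sedentary samples, a difference of -3.79 in place of -7.08 (exact p = 0.00649), and the first component computed without it differed by -8.31 (exact p = 0.00216). Sedentary 17 stood apart from the other arrays, with pairwise correlations of 0.956 to 0.968, against 0.980 to 0.995 among the other 11 arrays.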

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

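In this part, the tests of single probe sets and of noise on sedentary 16 were chosen after the result was seen, as was the exclusion of the test of other atrial genes. A value was singled out when its gap to the nearest array of its group was too large a share of the group's range by Dixon's 95% critical value for 6 samples. This picked 11 of 134 groups tested, where chance picks about 1 in 20, and 7 of the 11 lie on sedentary 17 and 2 on sedentary 16.

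On sedentary 17, Adrb1 had an intensity of 1593 (other sedentary arrays 1018 to 1127), Kcnd2 798 (970 to 1043), Pam 11796 (14252 to 15556) and Ptp4a1 1625 (2030 to 2185). The same array had a median correlation with the other arrays of 0.964 (0.9857 to 0.9903), an SD of deviations from its group of 0.222 log2 (0.0980 to 0.114) and a value of 19.98 on the first principal component (-0.588 to 2.01). Pdk4 was at 1470 on exercised 9 (other exercised arrays 537 to 781). Xdh was at 1969 on sedentary 13 (other sedentary arrays 1445 to 1619).

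On sedentary 16, Myl7 was at 8652 (other sedentary arrays 1136 to 1923) and Myl4 at 2117 (844 to 1189). Nppa, which the rule did not single out, was at 26157 there (5870 to 11032). All 8 probe sets of Myl7, Myl4 and Nppa had their highest sedentary value on this array, and the 4 of Myl7 and Myl4 their highest of all 12, which argues against a fault of single probe sets for these genes, whereas exercised 4 was higher on 3 of the 4 Nppa probe sets with Myl7 at 1323 and Myl4 at 905, so high Nppa was not specific to sedentary 16. The SD of its deviations, 0.108 log2, lay within the 0.0838 to 0.114 of the arrays other than sedentary 17, which argues against a noisy array. Atrial tissue in the ventricle sample may account for the pattern, and of 10 other atrial genes fixed before their values were seen on single arrays, 0 were highest on sedentary 16. By the bound set beforehand this would count against atrial tissue. However, 6 of the 10 had a median intensity under 852, the median of the table, and 6 were highest on the noisy sedentary 17, so the count itself has little to show. The brighter ones, Cacna1g, Gnao1, Adm and Kcnj5, ranked 10, 6, 4 and 12 from the top of the 12 arrays on sedentary 16. These 4 genes did not stand out there, nor did Pam, at 14252 to 15556 on the sedentary arrays other than 17, while Myl7 and Myl4 go with atrial tissue. The 4 genes had medians of 874 (Kcnj5) to 1569 (Cacna1g) on the other arrays, and Pam was bright on all of them. A small atrial share could leave such signals unmoved, so these genes do not decide the question. Atrial tissue thus stays open, and no biological explanation was tested, since the labels give none for a single sample.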

How the results depend on the processing

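Alternatives that leave out sedentary 16 and 17, or exercised 4 and 5, were chosen after seeing the data; the others were fixed beforehand. The number of probe sets past the threshold (main 21; 18 higher, 3 lower) moved with the filter to 32 (9 lower) without one and 50 (41 higher, 9 lower) at the 50th percentile, settings that test more and fewer probe sets. Quantile normalization gave 6 lower, eBayes without trend 42 (37 higher, 5 lower), array weights 160 (109 higher, 51 lower) and a threshold of 0.10 gave 144 (115 higher, 29 lower). The exact rank-sum test gave 0 (0 higher, 0 lower), because its smallest possible p, 0.00216, becomes an adjusted 0.104 here; 989 were at an unadjusted p under 0.05 by it. Without sedentary 16 and 17 there were 5 (5 higher, 0 lower) and without exercised 4 and 5 there were 4 (4 higher, 0 lower), with fewer samples. With 1 array left out the counts ran from 3 to 37 (higher 3 to 32, lower 0 to 11), and the number at an unadjusted p under 0.05 from 839 to 1246. The 21 probe sets were all kept under both pseudocounts, the floor, no filter, no trend, robust eBayes and array weights, and 20 of them under quantile normalization, median scaling and the 50th percentile filter. Gene lists called (main 1) were 0 with an estimated correlation, 2 with fry, 2 with the mean of all probe sets, 8 at 0.10, 3 without sedentary 16 and 17, 2 without exercised 4 and 5, and 1 to 5 with 1 array left out; the ribosomal list was among them in each setting with a call. With arrays left out and the correlation estimated, a combination chosen after seeing the data, 0 were called in any of these fits.

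Some values changed sign. With array weights Igf1 was 0.072 and Sod2 -0.10. Without sedentary 16 and 17, Myl7 was 0.014, Igf1 0.025 and Sod2 -0.091. Without exercised 4 and 5, Cebpb was 0.015, Cpt1b 0.039 and Nppa -0.010. With 1 array left out, Cpt1b ran from -0.028 to 0.029, Cebpb from -0.031 to 0.021, Sod2 from -0.10 to 0.14, Igf1 from -0.043 to 0.039 and Myl7 from -0.48 to 0.039. The cause was not tested, except that Myl7 turned on sedentary 16. Hspe1, Xdh and Nmrk2 passed under every alternative run except the rank-sum test. Neither scaling moved the median of all probe sets by over 0.003. The fit with an RNA quality ratio as covariate was not run, and signal over background could not be judged without detection calls.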

Other observations

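In this part, the tests of the ribosomal list against matched random lists and without single arrays, all tests of clock genes, the test of lysosomal genes and the count of splits in either direction were chosen after the result was seen.

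Some lysosomal genes outside the named ones, picked after their values were seen, had higher values in exercised samples, and none of them passed. Among the named genes, the lysosomal gene Gm2a was lower (log2 difference -0.23, limma adjusted p = 0.0920). The lysosomal protease Ctss went from 1265 ± 190 to 1906 ± 497 (log2 difference 0.46 ± 0.12, SE, n = 6, limma adjusted p = 0.0916). The lysosomal lipase Lipa went from 2832 ± 431 to 3591 ± 683 on its brightest probe set (0.30 ± 0.12, 0.234), and its other ones gave 0.38 (0.0542) and 0.30 (0.169). The granulin gene Grn gave 0.13 ± 0.072 on its brighter probe set (0.396) and 0.24 (0.0584) on the other. Lyz2 was highest on exercised 4, at 9078, as was Col3a1, at 16171 against 5370 to 9526 on the other exercised arrays.

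Whether lysosomal genes as a class may be higher was tested on 20 other lysosomal genes, of which 16 were higher by sign. Their median log2 difference was 0.0496, under the upper 95% bound of matched random lists, which ran from 0.0587 to 0.0624 over 10 draws. The cytosolic peptidase Tpp2 was first listed among them by mistake, and with it the median was 0.0596. Without 5 genes whose values had been tabulated in another list, the median was 0.00775, under its bound of 0.0637 to 0.0683. Of 100 splits of the arrays, 2 gave a median as far from 0, the real one included, with 0.0556 as the highest other. No gene of the 20 passed over all probe sets, and over the list alone 4 were higher (Fuca1 0.23, Cd63 0.23, Atp6ap1 0.17, Ctsl 0.16) and Psap lower (-0.23), so a general increase was not shown. By the rule first set, a median under the upper bound of random lists would count against one, but this rule was changed after the result was seen, since a median above 0 does not exclude a small increase, which stays open.

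Chance as the source of the counts was tested on 100 of the 462 splits of the 12 arrays into 6 and 6, the real one included. As many probe sets passed in 1 split, the real one (21, highest other 8), as many as its higher ones in 1 (18, highest other 6) and as many as its lower ones in 2 (3, highest other 6), where the other splits count by the larger of their 2 directions, since which side is called higher is arbitrary. As many at an unadjusted p under 0.05 were found in 1 split (1060, highest other 1032). Each of these counts was reached in a share of the drawn splits under 0.05, which argues against chance as their source without excluding it. This is weakest for the lower probe sets, of which another split had more, and for the unadjusted count, which another split nearly reached. By contrast, 81 of the 100 splits called at least as many gene lists as the real 1, with 9 as the highest other. The number of lists thus gives no evidence against chance.

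For the ribosomal genes the list median of 0.147 lay above the 0.0615 that bounds random lists of like expression, which argues against a shift of all bright probe sets. Other lists left their ranges too, in both directions, among them fibroblast markers (0.144 against 0.0737). Random lists do not keep the correlation between genes, so leaving the range does not weigh against chance. The ribosomal median was 0.108 after quantile normalization, and its lowest value with 1 array left out was 0.129 (without sedentary 24), which argues against the scaling or 1 array alone. Of 100 splits, 1, the real one, gave a median as far from 0, but the highest other reached 0.141, and these genes vary together between arrays (estimated correlation 0.286). A modest increase with training may explain the pattern as a hypothesis, and a difference in RNA handling between groups stays open, since the RNA quality check could not be run.

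For the clock genes, a difference in clock phase between samples was tested within groups. With 1 array left out, 0 of 48 differences between the groups changed sign. The genes were chosen because they differed, so a sign could hardly turn, and this says little on 1 array alone. The difference of Dbp ran from 0.61 without exercised 8 to 0.96 without exercised 4. With group means removed, Bmal1 on its brighter probe set went against the mean of Dbp, Nr1d2 and Bhlhe41 (Per2 was under the filter) over the 12 samples, with Pearson r = -0.817 (one-sided permutation p = 0.00011) and Spearman rho = -0.888 (p = 6e-05), both adjusted to 0.00055 over 10 correlations; r was -0.785 without the 2 farthest samples, -0.970 within exercised and -0.830 within sedentary. The dimmer Bmal1 probe set gave r = -0.670 and rho = -0.643 (permutation p = 0.00867 and 0.0153, adjusted 0.0124 and 0.0192), -0.576 without the 2 farthest samples, -0.962 within exercised and -0.425 within sedentary, and went with the brighter one within exercised (r = 0.957) but not within sedentary samples (-0.068), with r = 0.286 and rho = 0.364 over all (permutation p = 0.420 and 0.288, adjusted 0.420 and 0.320) and 0.784 without the 2 farthest. The mean of the 3 genes went with the number in the sample's label (r = 0.754, rho = 0.811, two-sided permutation p = 0.00116 and 0.00067, adjusted 0.0029 and 0.00223; r was 0.697 without the 2 farthest, 0.823 within exercised and 0.871 within sedentary), and Bmal1 against it (r = -0.774, rho = -0.825, p = 0.00864 and 0.00479, adjusted 0.0124 and 0.00958, -0.729 without the 2 farthest, -0.795 and -0.764 within the groups). The samples may thus differ in clock phase, less firmly so among sedentary samples. On sedentary 17, the array that stood apart, the brighter Bmal1 probe set had its highest sedentary value (1232) and the dimmer one its lowest (415). The weaker values within sedentary samples may rest on this array, and the correlations without it were not computed. The samples may have been taken or handled in an order that the numbers follow within groups, but the labels give no times or order. The numbers of the groups do not overlap. Sedentary samples had the higher numbers (13 to 24 against 1 to 9) but lower mean Dbp, Nr1d2 and Bhlhe41 and higher Bmal1. This argues against 1 steady trend along all numbers as the source of the group difference. Whether training or the time of sampling sets the difference stays open.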
